A study of Mus musculus with 10 samples.

How the data were processed

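The samples were 10 Affymetrix arrays of cultured mouse ureteric buds, 3 with and 2 without GDNF on each of 2 array types. Groups and sample numbers were taken from the titles. Per the labels' protocols, total RNA from batches of 30 to 40 buds was pooled, about 5 to 6 batches to an array, amplified by in vitro transcription and labelled with biotin. The deposited value tables hold 1 intensity per probe set and array on a linear scale, with 12488 probe sets on U74Av2 and 22690 on 430A. Per the series text, the authors compared the groups in dChip 1.3. The text also states that different pooled samples were used for each chip. The normalization and expression summary behind the intensity values are not given in the sources used here. The authors' deposited comparison tables give, for the probe sets that passed their filter, a signed fold change (unit score here, since falls carry a minus sign) with its bounds and the difference of means. The folds on 430A matched the ratio of means of the deposited intensity values with a median log2 difference of 0.0046. On U74Av2 the median was 0.024 and the largest 0.845, so the means behind that table differ for some probe sets from those of the values.

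Gene names were taken from the authors' comparison tables, as Entrez identifiers, and were brought to current symbols with the RefSeq gene table of GRCm38.p6, used for names only. On U74Av2, 292 of the 312 listed probe sets had exactly 1 current protein-coding gene (275 genes), 6 had several and 14 none. On 430A, 661 of 693 had exactly 1 (543 genes), 7 had several and 25 none. Probe sets with several or none were not named, and probe sets outside these tables are unnamed here. Every gene-level result therefore covers genes that the authors had selected for change on the same arrays, 184 of them on both types. This departs from the plan, which assumed names for all probe sets. Because of it, the Benjamini-Hochberg adjustment of the fit over both types counted all 10588 U74Av2 tests, giving the unnamed ones a p of 1, a choice made after the files were seen. The moderated variance of that fit was learned from the selected genes alone. The authors' filter on the bound of the fold favours genes with little spread between these same arrays. The p-values of that fit may therefore be too small even with separate pools.

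Intensities below a floor were set to it, the 20th percentile of each table (65.0 on U74Av2 and 143 on 430A), and log2 was taken. Control probe sets (66 on U74Av2, 64 on 430A) and probe sets at the floor on all 5 arrays (1834 and 3105) were left out, leaving 10588 and 19521. A fold against a group with every array at the floor is a lower bound, computed against the floor. Each type was fitted alone in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit over both types used the named probe set with the highest mean for each gene and type, with array type as a fixed term, so levels were never set across the tables. The interaction of type and GDNF tested the difference between types, adjusted over the 184 genes. SE values are limma's moderated standard errors, and p-values printed without another test's name are from limma. Gene lists fixed before the data were examined (20 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were named. Camera compares a list with the other genes of the fit, here the other selected genes. The fold-change filter was recomputed with Fieller's bound from the arrays' spread, since dChip's own errors per array are not used here. Control ratios were compared by exact permutation.

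Named genes followed a rule fixed at the same time. It took the 12 core GDNF/Ret genes, and the 12 largest rises and 12 largest falls past the threshold over both types with the same direction on each. Among genes on 430A only it took the 8 largest rises and falls past the threshold or, where fewer than 3 passed in a direction, the 3 with the smallest p. It also took the 3 members of each list with the smallest p over both types and the 5 largest rises and falls of each authors' table. Clone names and predicted genes were passed over.

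Alternatives planned beforehand were quantile normalization, median centring, floors at the 10th and 40th percentiles, probe sets above the median level, a trended robust variance, an adjusted p of 0.1, sample number as a block, leaving out each array, the mean over a gene's probe sets, a random block shared between types, other set tests and other filter limits. Alternatives added after the data were seen were a block and an exclusion for plus sample 3 and minus sample 2, the Gapdh ratio as a covariate, averaging of same-named arrays, no moderation, and adjustment over the named genes alone. Leaving out 1 minus array leaves a lone one, assumed to vary like the plus arrays. Some members of the gene lists were counted in the tests and are not reported here by name.

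The methods were tested on simulated data with 200 changed items. For 430A (19521 probe sets, 3 against 2), limma recovered 69 of 100 changes of 1 log2 unit and 97 of 100 of 2 units, with 9 false calls. For U74Av2 (10588) it recovered 34 and 78 of 100, with 2 false calls. For the fit over both types (2000 genes), separate pools gave 98 and 99 of 100 with 6 false calls. When the same pools were simulated on both types (correlation 0.5), the fit made 51 false calls and 11.2% of unchanged genes had an unadjusted p under 0.05. Averaging same-named arrays then made 6 false calls and a random block 9. The 2000 genes were mostly unchanged, took their spread from the selected genes and were adjusted over 2000 tests. The real fit held 184 genes selected for change on the same arrays, adjusted over 10588. These runs therefore do not give the power or error of the real fit. The recomputed filter recovered 82 and 100 of 100 on 430A with 58 false passes, and 57 and 77 of 100 on U74Av2 with 61. For camera (184 genes), a list of 33 genes shifted by 0.5 was found in 50 of 50 runs and an unshifted list in 0. In those runs the other genes were unchanged and independent, whereas nearly all of the real ones changed. The runs therefore do not give the power or error of the camera tests below.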

Results

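Ureteric buds were isolated from Swiss Webster mouse embryos at E11.5 and grown in Matrigel, a gel of basement membrane proteins. The ureteric bud is the epithelial outgrowth that branches to form the collecting system of the kidney. The buds were cultured for 16 h with 100 ng/mL GDNF, the growth factor that signals through the receptor tyrosine kinase Ret, or without it. Each array carried RNA pooled from about 5 to 6 batches of 30 to 40 buds. U74Av2 and 430A, which are Affymetrix short oligonucleotide arrays, each had 3 plus GDNF arrays and 2 minus GDNF arrays, 10 arrays in 4 groups. The median deposited intensity lay between 211 and 248 on the U74Av2 arrays and between 281 and 321 on the 430A arrays. The number of arrays limits the precision of every value here, and p-values measure the spread between arrays. Those over both types count the 10 arrays as separate pools, as the series text states. If same-named arrays of the types shared pools, which was not settled, those p-values are too small. They may be too small in any case, since the genes and the moderated variance rest on the authors' selection from these same arrays.

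The first comparison asked which genes GDNF regulated in the bud, over both array types together. The genes that rose included several known from Ret signalling at the branching tip. Wnt11, a secreted signal of the bud tip, rose in the fit over both types (log2 at least 2.37, adjusted p = 0.0048), and with each sample name as a random block shared between the types it had adjusted p = 0.16. It was at least 13.1-fold higher on U74Av2 and 2.05-fold higher on 430A. Cxcr4, the receptor of the chemokine Cxcl12, rose at least 4.02-fold (log2 at least 2.01, adjusted p = 1.1e-04). Ret itself rose 3.10-fold (log2 1.63 ± 0.23 SE, adjusted p = 0.0014), from an intensity of 184 ± 29.8 (SD, n = 2) to 536 ± 176 (SD, n = 3) on 430A. Dusp6, a phosphatase that acts on ERK, rose 3.15-fold, and the ETS transcription factor Etv4 rose 2.79-fold. Myb, another transcription factor, rose 2.22-fold (log2 1.15 ± 0.15). The minus GDNF arrays lay below the intensity floor for Wnt11 on U74Av2 and for Cxcr4 on both types, so these folds and both log2 changes are lower bounds. With the floor at the 40th percentile, Myb had log2 0.23 and did not pass.

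**Figure D1:**
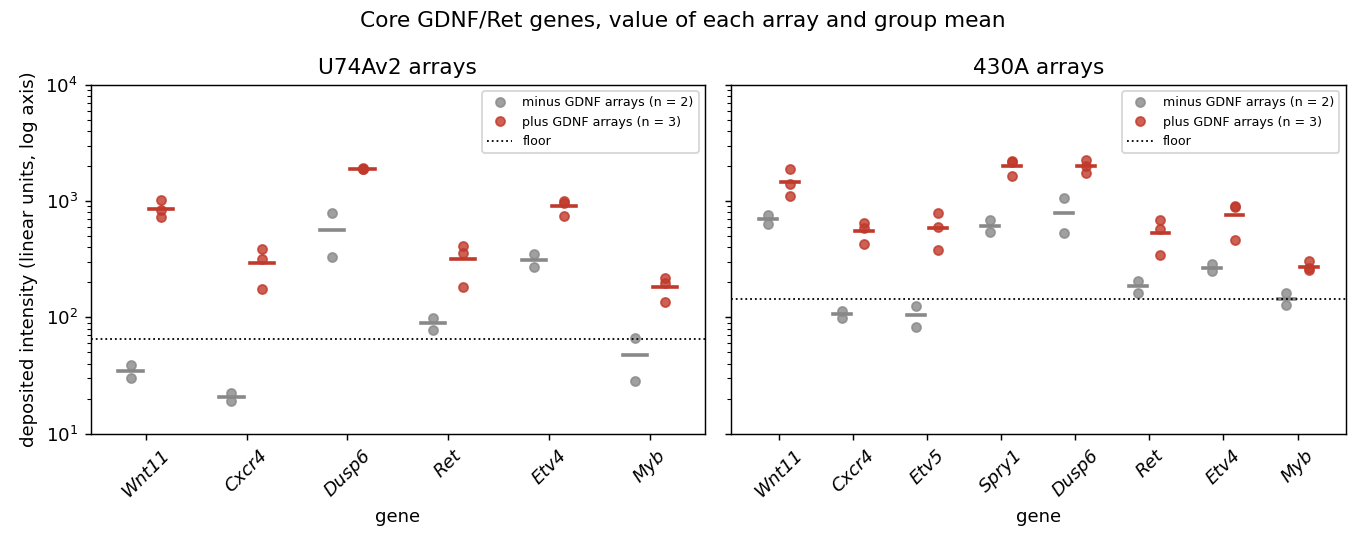
Deposited intensity (linear units on a log axis) of core GDNF/Ret genes on the U74Av2 arrays (left) and the 430A arrays (right), with 1 point per array, bars at the group means and a dotted line at the floor. Each plus GDNF array lay above each minus GDNF array for every gene shown, as for Ret on 430A with means of 536 and 184.

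All 7 members of the core GDNF/Ret list that were named on both types rose (median log2 1.66), and 7 passed when adjusted over the list alone. The list was partly chosen from what the study is known to have reported on these samples and is not independent evidence of direction. Etv5 and Spry1 were named on 430A only. Etv5, an ETS factor, was at least 3.93-fold higher there (adjusted p = 0.084), and Spry1, a feedback inhibitor of receptor tyrosine kinases, was 3.27-fold higher (adjusted p = 0.054), with neither past the threshold. Gfra1, Met and Mmp14 had no named probe set and were not analysed here. The ureteric bud tip list held the same 7 genes on both types, and on 430A alone it added Sox9 at log2 0.62 ± 0.13 (adjusted p = 0.14). Of all 184 genes named on both types, 183 passed over both types, so a count of passing members says little about a list. The ERK feedback and response list holds 44 genes, of which 4 were named on both types. All 4 rose and 4 passed adjusted over the list alone. They were Dusp6, Etv4, Ccnd1 (cyclin D1, log2 1.59 ± 0.19) and the Ras-ERK inhibitor Spred2 (log2 1.37 ± 0.16). Against the other named genes, camera over both types gave adjusted p = 0.37 for the core and bud tip lists and 0.45 for the ERK list. On 430A, Spry2 stood at log2 1.08 ± 0.12 (adjusted p = 0.054) and Spred1 at 0.53 ± 0.11 (adjusted p = 0.14). Sox9, Spry2 and Spred1 were singled out after their values were seen.

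Of the fixed lists, that of the cell cycle and DNA replication had the most named genes. That list holds 62 genes, of which 33 were named on both array types. All 33 rose, with a median log2 change of 1.02, and 33 passed adjusted over the list alone. Of all 184 genes named on both types 183 passed, so this count says little about the list. Mki67, a marker of cycling cells, rose 2.49-fold (log2 1.31 ± 0.13), and the mitotic cyclin Ccnb2 rose 2.39-fold (log2 1.26 ± 0.11). Uhrf1, needed to maintain DNA methylation at replication, rose 2.32-fold, and Birc5 (survivin) rose 2.09-fold (log2 1.07 ± 0.09, adjusted p = 6.3e-05). On 430A all 47 named members were higher with GDNF, against 369 of the 496 other named genes (74.4%). Camera placed the list above the other named genes on 430A (adjusted p = 6.1e-04) and on U74Av2 (adjusted p = 0.029). With an estimated correlation the adjusted p was 0.45 and 0.60 on these types. In the fit over both types camera gave adjusted p = 0.095, and adjusted p = 0.67 with an estimated correlation. The comparison genes in these tests were themselves selected for change by the authors.

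Other large rises were those of Arg2, the mitochondrial arginase (log2 1.73 ± 0.13), Mtm1, the phosphoinositide phosphatase myotubularin (log2 1.62 ± 0.11), and Ect2, a protein needed for cytokinesis (log2 1.35 ± 0.10). The ER stress and amino acid response list holds 30 genes, of which 3 were named on both types, and all 3 rose. Psat1 of serine synthesis rose by log2 0.99 ± 0.14, Asns, which makes asparagine, by 0.90 ± 0.14, and the amino acid transporter Slc7a5 by 0.87 ± 0.12. All 8 members of that list named on 430A were higher with GDNF, against 408 of the 535 other named genes (76.3%), and camera gave adjusted p = 0.10 there and 0.58 over both types. They included Phgdh and Cth, enzymes of serine and cysteine synthesis, at log2 0.68 and 1.08, and Dnajc3, a co-chaperone of the endoplasmic reticulum, at 0.70. None of these 3, singled out after their values were seen, passed the threshold on that type alone. The 3 genes that rose act in amino acid synthesis and transport. The glucose transporter Slc2a1 was the 1 named member of the hypoxia and glycolysis list and rose by log2 0.66 ± 0.11. Idi1 of isoprenoid synthesis was the 1 member of the cholesterol list in the fit and rose by 0.96 ± 0.19. Without 430A minus array 2, Idi1 had adjusted p = 0.089 (log2 0.86). Each of these lists had as many genes past the threshold when adjusted over the list alone.

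The falls were smaller and fewer. Wnt4, a Wnt ligand that drives the mesenchyme to form epithelium, fell by 0.90 ± 0.13 on the log2 scale (adjusted p = 0.0014). Dlk1, a membrane protein related to Notch ligands, fell by 0.86 ± 0.11, the serine protease Tmprss2 by 0.78 ± 0.12, and the nucleoside transporter Slc29a1 by 0.74 ± 0.13. Dkk1, a secreted Wnt antagonist, fell by 0.74 ± 0.14. The matrix protein Sparc fell by 0.68 ± 0.09, the surface protein Thy1 by 0.68 ± 0.09 and the adhesion molecule Ncam1 by 0.67 ± 0.11. C1qtnf12 fell by 0.68 ± 0.12 and Anxa1 by 0.64 ± 0.12. With each sample name as a random block shared between the types, Slc29a1 had adjusted p = 0.089, Dkk1 0.28 and Anxa1 0.11. Without 430A minus array 1, Dkk1 had adjusted p = 0.071 and Anxa1 0.070, and without 430A minus array 2, Dkk1 had adjusted p = 0.079. With array medians centred, C1qtnf12 had adjusted p = 0.053 and Anxa1 0.071. Of the Wnt/beta-catenin target list, Ccnd1 and Tcf7 (log2 0.91 ± 0.16) rose and Dkk1 fell. Its median was 0.91 while camera's direction against the other named genes was down, with adjusted p = 0.37. Of the heat shock list, Hspa1b, an inducible Hsp70, fell by 0.86 ± 0.15, whereas Hsph1 (log2 0.67 ± 0.11) and Hspe1 (log2 0.60 ± 0.09) rose. That list's median was 0.60, and camera's direction was again down, with adjusted p = 0.37. Adjusted over the list alone, all 3 genes of each of these 2 lists passed. Of the ureteric trunk and collecting duct list, Calb1, a calcium-binding protein of the bud and duct, rose by log2 0.85 ± 0.12.

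**Figure D2:**
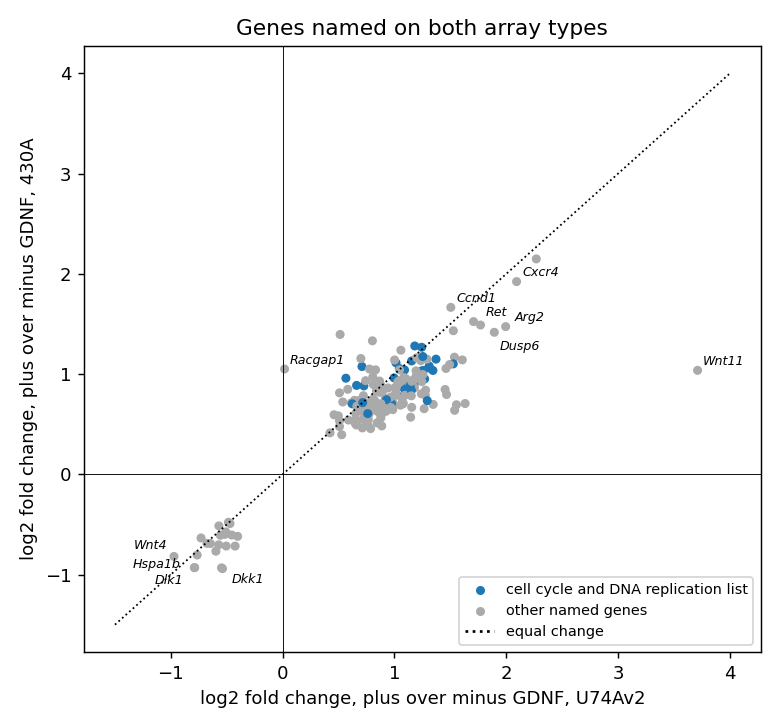
Log2 fold change of plus over minus GDNF on U74Av2 (horizontal) against 430A (vertical) for the 184 genes named on both array types, 1 point per gene, with the cell cycle and DNA replication list in blue and the dotted line at equal change. Pearson's r across genes was 0.871, and Wnt11 lay furthest from the line, at 3.71 (a lower bound set by the floor) and 1.04.

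Over both array types, 162 of 184 named genes rose and 21 fell, by limma with adjusted p under 0.05 over 10588 tests. Racgap1, singled out after its values were seen, was the 1 gene that did not pass, with log2 0.02 on U74Av2 and 1.05 on 430A. Median log2 changes were 0.90 among the rises and -0.64 among the falls. The names came only from the authors' deposited tables of changed genes, so these 184 genes were chosen on the same samples and the share that passed is no estimate for the genome. Same-named arrays of the types deviated from their group means together, with correlations across genes of at least 0.408. Averaging them to 5 samples, a choice made after the data were seen, left 147 rises and 11 falls, all among those above, with Anxa1 (adjusted p = 0.052) and Hspe1 (0.054) not past the threshold. Without limma's moderation of the variance, that average called 0 genes, and 178 had an unadjusted p under 0.05. With the arrays kept apart and no moderation, a fit added after the data were seen, 135 genes passed. Of the genes named here, Ret (adjusted p = 0.067), Dusp6 (0.066), Wnt11 (0.17), Hspa1b (0.12), Slc29a1 (0.078), Dkk1 (0.16), C1qtnf12 (0.066), Anxa1 (0.11), Idi1 (0.24) and Tcf7 (0.10) then did not pass.

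Among genes named on 430A and not on U74Av2, none passed limma's adjusted p of 0.05. The smallest p-values among higher genes belonged to Ncapg, a condensin subunit (2.87-fold, log2 1.52 ± 0.10), the uracil DNA glycosylase Ung (2.44-fold) and Cep55, a protein of the cytokinetic midbody (2.17-fold), each with adjusted p = 0.054. Among lower genes they belonged to the small heat shock protein Hspb1, Ppp1r3c, which targets phosphatase to glycogen, and Tma16. Hspb1 measured 1809 ± 140.0 (SD, n = 3) with GDNF and 4045 ± 40.6 (SD, n = 2) without (log2 -1.16 ± 0.11, adjusted p = 0.054). Ppp1r3c stood at log2 -0.99 ± 0.11 (adjusted p = 0.054) and Tma16 at -0.77 ± 0.09 (adjusted p = 0.060).

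Markers of other cells that a dissected bud could carry were measured beside these groups. On 430A the stromal markers Vim (log2 -0.62 ± 0.15), Postn (-0.60 ± 0.12) and Tcf21 (-0.66 ± 0.24) were lower with GDNF. So were the mesenchymal markers Cited1 (-0.51 ± 0.10) and Cdh11 (-0.49 ± 0.15), and none of these passed the test. They were 3 of 20 listed stromal and 2 of 17 listed mesenchymal genes, and the others had no named probe set there. Of the 19521 probe sets tested on 430A, 0 passed, so not passing says little about these markers or the list genes below. Acta2, named on U74Av2 alone, stood at -0.41 ± 0.20 there. The level of Vim was 1021 ± 157 (SD, n = 3) with GDNF and 1560.5 ± 29.7 (SD, n = 2) without. Camera put the 3 stromal genes below the other named genes on 430A (adjusted p = 0.019), and adjusted p = 0.45 with an estimated correlation. Of the general bud epithelium list, Krt8 (-0.52 ± 0.14), Cdh16 (-0.92 ± 0.24) and Npnt (-0.77 ± 0.19) were lower and Lhx1 (0.64 ± 0.11) was higher, with 0 of 4 past the test. No member of the endothelium list or of the blood and macrophage list was named, out of 13 and 19 genes. On 430A, 3 p53 and apoptosis genes were named and 0 passed, Cdkn1a at -0.60 and Btg2 at -0.49 among them, and Gadd45b stood at -0.57 on U74Av2. Of the matrix, protease and adhesion list, Itga6 (0.63), Timp2 (-0.55) and Npnt were named and did not pass. Bambi (-0.51) was the 1 named TGF-beta and BMP gene and Neo1 (0.57) the 1 axon guidance gene, neither past the test. These marker and list genes were singled out after their values were seen.

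**Figure D3:**
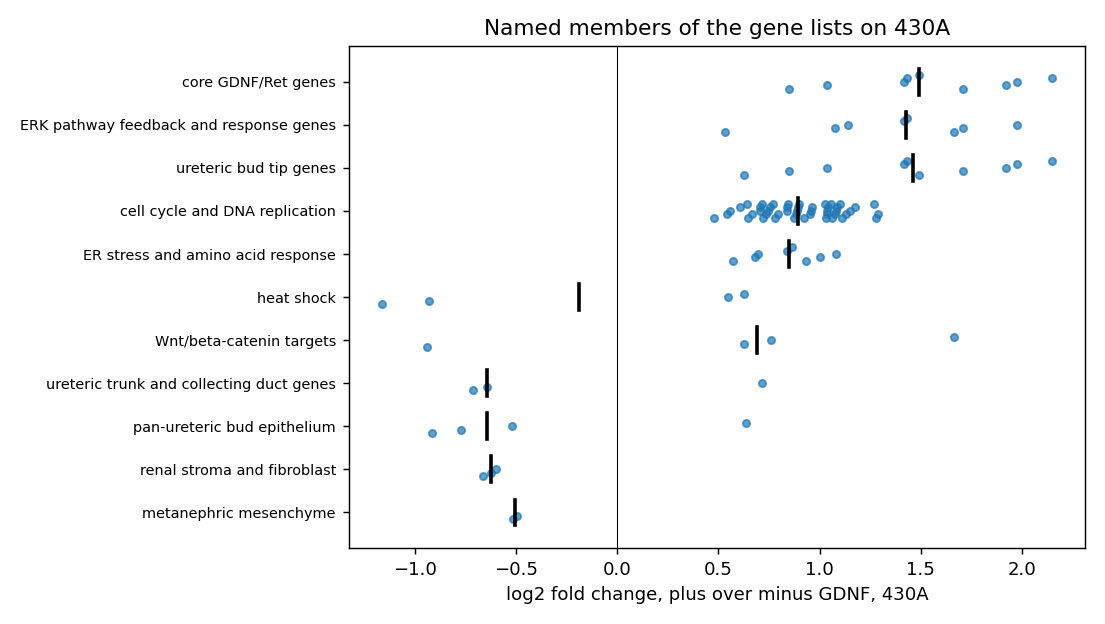
Log2 fold change on 430A, plus over minus GDNF, of the named members of 11 gene lists, 1 point per gene and a black bar at the median. All 47 named cell cycle genes (of 62 listed) lay above 0. The 3 named stromal genes (of 20 listed) and 2 named mesenchymal genes (of 17 listed) lay below 0.

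Each array type was also tested alone over all its probe sets, with 3 plus against 2 minus arrays. On U74Av2, Wnt11 alone rose past the threshold of limma's test of 10588 probe sets (adjusted p = 0.011), from 34.7 ± 6.31 (SD, n = 2), below the floor of 65.0, to 860.2 ± 149 (SD, n = 3), at least 13.1-fold. On 430A limma called 0 of 19521 probe sets, with a smallest adjusted p of 0.054. At an adjusted p under 0.1 there were 5 probe sets on U74Av2, all higher with GDNF, and 198 on 430A, 176 higher and 22 lower. At an unadjusted p under 0.05 there were 931 on U74Av2 and 2588 on 430A, against 529.4 and 976 that chance gives. On U74Av2 limma made 0 calls without plus array 1 (517 probe sets at an unadjusted p under 0.05), plus array 2 (561), minus array 1 (2098) or minus array 2 (566). On 430A the number at an unadjusted p under 0.05 was 6729 without minus array 1, 1371 without plus array 2 and 1661 without minus array 2.

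The change differed between the array types for 1 of 184 genes by the interaction test. Wnt11 measured 1457 ± 391 (SD, n = 3) with GDNF and 696 ± 84.3 (SD, n = 2) without on 430A, log2 1.04 ± 0.23. Its change there was smaller than on U74Av2, by a log2 difference of at most -2.67 (adjusted p = 1.7e-04), which is a bound set by the floor because the U74Av2 minus arrays lay below it. With the floor at the 40th percentile the interaction test called 0 genes. No other gene of the 184 passed, and 12 had an unadjusted p under 0.05. Across genes, the changes on the 2 types correlated with Pearson's r of 0.871 and a Spearman correlation of 0.707, and all 184 had the same sign on both. Genes are not independent replicates, and these had been selected for change on each type. Without U74Av2 minus array 1 the interaction test called 5 genes.

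The filter that the series describes asks for a fold change whose lower 90% bound exceeds 1.2 and a difference of means over 100. Recomputed from the deposited intensities, 257 U74Av2 probe sets passed as higher and 23 as lower, and on 430A 380 as higher and 106 as lower. The authors' deposited table for U74Av2 lists 312 probe sets, 273 higher and 39 lower with GDNF, and the authors' deposited table for 430A lists 693, 542 higher and 151 lower. In the authors' deposited table for U74Av2, the largest rises included those of Wnt11 (27.4-fold), Cxcr4 (14.8-fold), Arg2 (4.24-fold) and Myb (3.86-fold). In the authors' deposited table for 430A they included those of Etv5 (5.52-fold), Cxcr4 (5.17-fold), Myb (3.27-fold) and Spry1 (3.26-fold). The largest falls in the authors' deposited table for U74Av2 belonged to Znrf2 (-2.38-fold), Wnt4 (-2.19), Dlk1 (-1.89), Ncam1 (-1.86) and Hspa1b (-1.82). In the authors' deposited table for 430A they belonged to Hspb1 (-2.23), the parathyroid hormone receptor Pth1r (-2.11), the iron exporter Slc40a1 (-2.09), Ppp1r3c (-1.99) and Igfbp7 (-1.98). Of the probe sets in the authors' deposited table, 207 on U74Av2 and 466 on 430A passed the recomputed filter, and 304 and 693 had an unadjusted limma p under 0.05. The recomputed filter gave 145 U74Av2 and 318 430A probe sets without minus array 2 of that type, and 1390 on 430A without minus array 1.

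RNA quality was read from the control probe sets as the ratio of the 3' to the 5' signal. The Gapdh ratio on 430A was 1.28 ± 0.217 (SD, n = 3) with GDNF and 1.42 ± 0.461 (SD, n = 2) without, and on U74Av2 1.25 ± 0.202 and 1.35 ± 0.356. No difference between the groups was detected by an exact permutation test (two-sided p = 0.7 on each type), but with 10 splits no p under 0.1 was possible. Plus sample 3 and minus sample 2 stood apart from the others on both types, with Gapdh ratios of 1.52 and 1.74 on 430A against at most 1.19 in the rest. The same samples had the highest hybridisation control signals. Each group held 1 of these samples, which was 1 of 3 plus arrays and 1 of 2 minus arrays on each type. With this pair as a block, a fit chosen after the data were seen, limma called 128 U74Av2 probe sets (123 up, 5 down) and 3 on 430A. With the Gapdh ratio as a covariate it called 267 (233 up, 34 down) on U74Av2 and 166 (146 up, 20 down) on 430A. Without the pair limma called 0 on either type, with 804 probe sets on U74Av2 and 1979 on 430A at an unadjusted p under 0.05. Over both types it then called 143 rises and 17 falls, with 31 of the 33 cell cycle genes and 6 of the 7 core genes. Among the named genes, Wnt11 (adjusted p = 0.056), Dkk1 (0.61), Anxa1 (0.067), Idi1 (0.090) and Hsph1 (0.31) then did not pass.

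**Figure D4:**
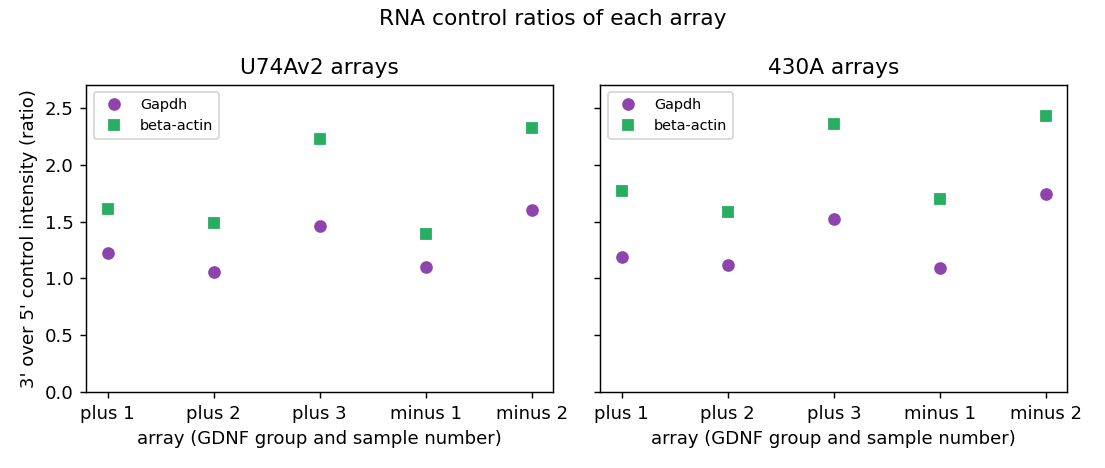
Ratio of 3' to 5' control intensity for Gapdh (circles) and beta-actin (squares) on each array, U74Av2 left and 430A right, with the arrays named by GDNF group and sample number. Plus sample 3 and minus sample 2 had the highest ratios of both controls on both types, for Gapdh 1.46 and 1.60 on U74Av2.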

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

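The interaction test was planned, and the tests with a block for RNA quality and with other splits of each type's arrays were chosen after the result was seen. Wnt11 changed differently on the 2 array types by the interaction test, with a log2 fold change on 430A lower than that on U74Av2 by a difference of at most -2.67. This is a bound set by the floor, since on U74Av2 its minus GDNF arrays lay below the floor. On 430A they measured 696 ± 84.3 (SD, n = 2), well above that type's floor of 143. With the floor at the 40th percentile the interaction called 0 genes. Groups of 3 or fewer arrays were not tested for outlying samples. Across probe sets, minus sample 2 correlated least with the other arrays, at 0.916 to 0.960 on U74Av2 and 0.930 to 0.957 on 430A. All other pairs of arrays stood at 0.966 or more on U74Av2 and 0.967 or more on 430A. Minus sample 2 is 1 of the 2 minus arrays of each type.

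Both array types held more probe sets with small p-values than chance gives, 931 on U74Av2 and 2588 on 430A. A difference in RNA quality or hybridisation between samples did not follow the groups alone, since plus sample 3 and minus sample 2 shared it. It was not balanced between them either, as the pair held 1 of 3 plus and 1 of 2 minus arrays of each type. Mean Gapdh ratios were 1.25 with GDNF and 1.35 without on U74Av2, and 1.28 and 1.42 on 430A. With this pair as a block the counts were 1640 and 3398, above the 529.4 and 976 that chance gives. The block was chosen after the pair was seen to stand apart, and it removes only an equal shift of both its samples. Splits other than the real one also gave counts above chance. This test therefore does not decide whether that difference is a cause. Splits of the 5 arrays are too few, at 10, for a share under 0.05. On 430A the real split gave 2588 and the highest other 2338 (1 of 10 splits reached the real value), and on U74Av2 the real split gave 931 and the highest other 3500 (3 of 10). In both cases the highest other split parts plus sample 3 and minus sample 2 from the rest. On U74Av2 it called 516 probe sets at adjusted p under 0.05, against 1 for the real split, which points to a structure of the samples.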

How the results depend on the processing

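The directions of the 37 genes named over both types held under every setting tried, and 66 of their 956 values lost the threshold, 37 of them when same-named arrays were averaged without moderation. The 8 genes named on 430A alone kept their directions too, and 24 of 117 values passed it. The U74Av2 count of 1 became 5 at adjusted p under 0.1, 0 with the floor at the 40th percentile, 4 among probe sets above the median level and 3 with a trended robust variance. The 430A count of 0 became 198, 30 (floor at the 10th percentile), 149 and 48 (trended robust variance). In settings added after the data were seen, the U74Av2 count was 128 with the control-signal block, 267 with the Gapdh covariate and 0 without plus sample 3 and minus sample 2, and the 430A count was 3 with the block and 166 with the covariate. Leaving out each array gave 0 to 1 on U74Av2, 0 on 430A and 172 to 182 genes over both types. The 183 genes over both types became 0 when same-named arrays were averaged with no moderation, also added after the data were seen, where 3 residual degrees of freedom are left, and stayed within 1.5 times otherwise.

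Agreement between types, r = 0.871, was 0.845 with the floor at the 10th percentile, 0.898 at the 40th, 0.904 without plus sample 3 and minus sample 2, and 0.835 to 0.874 without each array. The interaction called 0 genes with the floor at the 40th percentile, 2 with the Gapdh covariate, and 1 to 5 without each array, 5 without U74Av2 minus array 1. Lists past the threshold numbered 1 at adjusted p under 0.1, 7 with fry, which does not compare a list with other genes, 2 on 430A alone and 3 on U74Av2 alone, and 0 without each array. With an estimated correlation the lists called on single types had adjusted p = 0.45 on 430A (cell cycle and stroma) and 0.60 on U74Av2 (cell cycle, core GDNF/Ret and bud tip). The filter gave 931 and 1921 probe sets (U74Av2 and 430A) with a bound of 1.0, 60 and 89 with 1.5, and 1658 and 3013 with the observed ratio. It gave 166 on U74Av2 without plus sample 3 and minus sample 2, and 145 to 377 and 318 to 1390 without each array. The authors' listed probe sets called by limma, 1 in all, numbered 200 at adjusted p under 0.1 and 997 at unadjusted p under 0.05. Looser limits, fewer tests or fewer samples are built into the settings that change them, and for the other settings the cause was not tested. Without 430A minus array 1, 1005 of the 1390 probe sets were lower.

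Whether sample numbers paired plus and minus arrays could not be settled, since the deviations of the 2 minus arrays of a type are opposite. Deviations of plus 1 and minus 1 correlated at 0.16 and -0.02 on the 2 types, and of plus 2 and minus 2 at -0.70 and -0.62, with only 2 pairs. With the sample number as a block the counts were 1 on U74Av2, 0 on 430A and 181 over both types, and the interaction called 2 genes. The blocked fit ended the call for Anxa1 (adjusted p = 0.062) and changed no other named call over both types. Signal near the floor limits folds of dim genes such as Myb, whose log2 change was 0.23 with the floor at the 40th percentile. For Myb on 430A the fit took the named probe set with the highest mean, which was 1.80-fold higher with GDNF. The 3.27-fold rise in the authors' deposited table for 430A belongs to another Myb probe set.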

Other observations

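The tests in this part of pools, selection and cell types were chosen after the values they measure had been seen, and that of the splits was not. The U74Av2 arrays named 5 members of the cell cycle list that 430A did not, Cdca8 (log2 1.44 ± 0.20), Cdc25c (1.10 ± 0.15), Cdc20 (1.02 ± 0.30), Mcm5 (0.92 ± 0.24) and Rfc3 (0.63 ± 0.17), each higher with GDNF and none past the threshold there. Cxcl12, the ligand of Cxcr4, stood at 0.66 ± 0.18 on U74Av2, also not past it. All were named after their values were seen.

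Fold changes ran together on the array types. Deviations of same-named arrays from their group means correlated across the 184 genes at 0.408 or more (the 2 minus pairs share 1 value, 0.451, as deviations from a mean of 2 are opposite), and those of arrays of different groups at 0.18 at most. Profiles of 9 hybridisation control probe sets were nearest to the same-named array for 5 of 5 U74Av2 arrays and 4 of 5 430A arrays, while the 430A minus 2 array lay nearest to U74Av2 plus 3. This is consistent with the same RNA pools on both types, a hypothesis, and the 10 arrays may then hold 5 independent pools. Selection cannot be told apart from agreement, since all 184 of 184 genes had the same direction and were listed by the authors on both types.

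On 430A the 3 named stromal and 2 named mesenchymal markers, of 20 and 17 listed, had lower values with GDNF, with Vim at 1021 against 1560.5. The other listed genes had no name there, since names came only from genes that the authors listed as changed. None of the named markers passed the test, but neither did any other probe set on 430A. A smaller share of stromal or mesenchymal cells in the plus samples may contribute, which would leave epithelial markers level or higher. The median of the 4 named epithelial genes was -0.64, but 12 of the 16 listed were not named here, so this cannot be told apart from a change within the bud. Of the called genes over both types, 1 of 100 splits of the arrays within each type reached the real count of 183, with 5 as the highest of the others, and because the genes were chosen by the real split this says nothing of chance.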
